A study of Mus musculus with 14 samples.

How the data were processed

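The study measured RNA in C2C12 cells, a mouse myoblast line that can differentiate into muscle, after transfection of small interfering RNAs (siRNAs) against Quaking (Qk). Qk is an RNA-binding protein made as isoforms with different C-terminal ends. Per the labels' protocols, cells were grown in DMEM with 10% fetal bovine serum, transfected with Lipofectamine 2000, and RNA was taken with TRIzol and depleted of ribosomal RNA with a RiboZero kit. The labels hold 14 samples in 4 groups: control, Qk5 depletion and Qk6/7 depletion with 3 replicates each, and pan-Qk depletion with 1 replicate. Replicate 1 of every group was sequenced in 2 runs. Nothing in the labels says that replicates came from separate cultures, so the p-values measure the spread between these samples, which may be technical. The pan-Qk samples were not analysed here.

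Per the submitters' processing notes, Bowtie2, TopHat2, SAMtools, bedtools and the authors' DESeq were used with the mm9 build, with no version given. How reads were counted, which strand setting was used, how the runs of replicate 1 were joined and which annotation defined the gene clusters are not given in the sources used here. The values are 3 deposited tables of the authors' own comparisons. Per the file headers, the expression table gives for each gene the authors' mean signal per condition (read counts divided by size factors), the fold (ratio of depleted over control mean), its log2, a p-value and an adjusted p-value from DESeq, and a direction score of -1, 0 or 1. Per the file headers, the splicing tables give for each exon bin, a stretch of exon that all transcripts of a gene use or skip together, the authors' log2 fold of bin use between conditions, a dispersion estimate, and 1 DEXSeq p-value and adjusted p-value over the 3 conditions together. A bin's log2 fold is thus not tested on its own in either depletion. The tables hold no value per replicate, so read depth per sample is unknown, no SD or interval can be given for a level or fold, and no count model was refitted.

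The expression table holds 1036 genes, those with adjusted p under 0.1 in at least 1 comparison. Adjusted values recomputed by the Benjamini-Hochberg method matched the deposited ones when 16604 genes were taken as tested for Qk5 depletion and 16564 for Qk6/7 depletion. The longer splicing table holds all 4019 bins of 228 genes that have a bin with adjusted p under 0.1, of which 3737 bins have an adjusted p. The shorter one repeats 231 of these bins, those under 0.05. By the same recomputation about 142000 bins had been tested. One expression row had its fields broken across columns and was rejoined, with a check that its smallest adjusted p equals the smaller of its 2 adjusted p. For 2 splicing genes the table holds a date in place of a symbol, and they are named by position only. Splicing coordinates are those of the authors' files (mm9). The reference used here is GENCODE M21 on GRCm38: of 202 splicing genes it names, 16 have their first bin inside their GRCm38 span, so no coordinate was carried between builds and the reference served only for 3′ UTR sequences by symbol.

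Genes and bins were called at the authors' deposited adjusted p of 0.05, with direction from the deposited fold. Named genes followed a rule fixed before the data were examined. Qk came first. Then came, for each comparison, the 10 largest rises and 10 largest falls in log2 fold among called genes at or above the table's median mean level of 275.5, and up to 4 called members of each of 19 gene lists. Among called bins the rule took the 10 largest rises and falls per depletion and every bin in Qk or a reported Qk target. Of the bins it took, 1 gene's are not reported here. For Qk5 against Qk6/7 depletion it took the 5 largest differences in each direction. Gene lists were compared with the other genes of the table by Fisher's exact test (two-sided) with Benjamini-Hochberg adjustment over lists with at least 3 members in the table. Because the table is cut at adjusted p under 0.1, a second test was added after the data were seen: a hypergeometric test against all genes tested, taking every list member as tested. Both list tests take genes as independent, while members of a list can move together, so their p-values can overstate the evidence. Counts adjusted over the list alone are lower limits, since members outside the table were treated as not significant.

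The expression table has no test of Qk5 against Qk6/7 depletion. An approximate test was added after the data were seen. It takes the standard error implied by the smaller of a gene's 2 deposited p-values, uses it for both log2 folds, ignores the covariance from the shared controls, and adjusts over 1033 genes. In data simulated for this comparison, with 4000 genes of which 100 differed by 1.5 on the log2 scale, it called 93 of the 97 differing genes selected and 3 of the 127 other genes selected. The simulation gave all genes the same dispersion and took it as known, so these rates may not hold for the data. Overlaps between depletions were tested by Fisher's exact test over 16564 genes, beside a simulation, added after the data were seen, of unchanged groups with shared controls (1000 draws of normal deviates correlated at 0.5), once at the p-value limits of the calls and once with as many genes taken at each end as were called. Words of 6 to 8 bases were counted in the longest annotated 3′ UTR of 884 genes of the table, against the number expected from UTR length, with 1000 permutations of genes. In 800 simulated sequences that search ranked a planted word 1st. Bins were placed in their gene from the complete bin set. Alternatives were an adjusted p of 0.01 or 0.1, genes at or above the median level, an absolute log2 fold of at least 1, and 1 bin per gene. Scripts used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6, Biopython 1.88 and matplotlib 3.10.9.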

Results

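RNA levels and exon use were compared between C2C12 myoblasts transfected with control siRNA, siRNA against the Qk5 isoform and siRNA against the Qk6 and Qk7 isoforms, with 3 replicates in each group. The question posed by the design was which RNAs change in level or splicing when 1 class of Qk isoform is depleted and which change with both. All levels, folds and adjusted p-values below are those of the authors' deposited table for each assay, which gives means without values per replicate. The depth per sample is unknown.

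Qk itself had a mean of 5875 normalized counts in control cells, 3267 after Qk5 depletion and 5271 after Qk6/7 depletion in the authors' deposited table. Its fold over control was 0.556 in Qk5 depletion (the authors' DESeq adjusted p = 0.00246) and 0.897 in Qk6/7 depletion (adjusted p = 1), as the authors' deposited table gives them. These are values for the whole gene, which do not separate the isoforms. No exon bin of Qk was among the called bins, and whether any was tested is not known here. Depletion of each isoform was therefore not checked.

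Depletion of Qk5 was followed mainly by rises. There were 360 genes that rose and 133 that fell at the authors' DESeq threshold in the authors' deposited table, so 73% of calls were upward. Among genes at or above the table's median mean level the counts were closer, with 129 raised and 91 lowered. Genes of differentiated muscle rose together: 14 of the 35 genes of the sarcomere list passed the authors' DESeq threshold, every one of them upward. Of 41 extracellular matrix genes 4 were also among the rises, a number that passed neither list test. Interferon-response genes were among the falls.

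Among genes at or above the table's median mean level of 275.5, the largest rise was that of Pdk1, a kinase that inhibits pyruvate dehydrogenase, at 3.50-fold in the authors' deposited table (the authors' DESeq adjusted p = 6.66e-13). Npnt, a matrix protein of basement membranes, rose 3.31-fold, and Mustn1, a small protein of the musculoskeletal system, 3.14-fold in the authors' deposited table. Dcn (decorin), which binds collagen, rose 2.95-fold, Slc40a1, the iron exporter ferroportin, 2.82-fold, and Mgam, an intestinal maltase, 2.81-fold, in the authors' deposited table. The 10 largest rises at such levels in the authors' deposited table were completed by Acta1, skeletal muscle actin (2.79-fold), Tmem150a (2.69-fold), the microfibril protein Fbn1 (2.66-fold) and Phex (2.55-fold), an endopeptidase that is also on the osteoblast list. The osteoblast list held 1 other gene of the table, which was not called in Qk5 depletion.

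Among genes at or above the median level, the largest falls were those of Laptm4b, a lysosomal membrane protein (0.362-fold), Dera (0.394-fold), Ccng1, the cyclin G1 gene and a p53 target (0.396-fold), and Tbcb, a tubulin cofactor (0.408-fold), in the authors' deposited table. Aldh3a1 (0.412-fold), Necap2 (0.425-fold), Ostm1 (0.429-fold), Psrc1 (0.431-fold), Cox6a1, a cytochrome c oxidase subunit (0.448-fold), and Ei24, another p53 target (0.451-fold), followed in the authors' deposited table. Of these 10 genes, 8 carried the word CTCTGAA or CCTCTGA in the annotated 3′ UTR, the exceptions being Aldh3a1 and Cox6a1. Lowered genes with either word did not fall further, with a median log2 fold of -0.91 against -0.98 without. Among the 119 lowered genes with an annotated 3′ UTR, 66.4% carried either word, against 28.5% of the other genes of the table (Fisher's exact test, two-sided, p = 4.85e-15), a p that overstates the evidence because the words were found in these same lowered genes.

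In the sarcomere list the authors' deposited table gives Mb (myoglobin) at 5.32-fold, Tnni1 (slow troponin I) at 3.32-fold, Mybph at 3.14-fold and Neb (nebulin) at 3.08-fold. These genes all lay below the median level, with Mb at a mean of 17.5 normalized counts in control cells and 93.0 in Qk5 depletion. Ttn, Tnnc1, Tnnc2, Mylpf, Myl1, Myh3, Casq2, Ckm and Xirp1 also rose in the authors' deposited table. Of the list's 17 members in the table, 82.4% were called against 47% of the other table genes (Fisher's exact test, adjusted p = 0.0289). The expectation among all genes tested was 1.04 called members (exact hypergeometric test, adjusted p = 1.72e-11), and adjusted over the list alone at least 17 rose. Both tests take the list's genes as independent, though they rose together, so these p-values can overstate the evidence. Myog (myogenin), a transcription factor of muscle differentiation, rose 2.54-fold (the authors' DESeq adjusted p = 0.00066), the 1 called member of the 20 myogenic regulators in the authors' deposited table. At adjusted p 0.05 with genes at or above the median level, the list test for the sarcomere genes had an adjusted p of 0.0808.

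Matrix genes called in Qk5 depletion were Dcn, Fbn1, Postn (periostin, 2.23-fold) and Col12a1 (2.02-fold), 4 of 41 members in the authors' deposited table (exact hypergeometric test, adjusted p = 0.155; Fisher's exact test within the table, adjusted p = 0.864; at least 7 rose and 1 fell adjusted over the list alone). Ctgf and Tgfb1 of the 20 TGF-beta targets rose 2.22-fold and 1.96-fold in the authors' deposited table. All 5 called interferon-response genes fell: Cxcl10, a chemokine (0.103-fold), Isg15 (0.165-fold), Ifit1 (0.190-fold), Rsad2 (0.231-fold) and Ifit3 (0.251-fold) in the authors' deposited table. All 5 lay below the median level, with Cxcl10 at a mean of 17.3 normalized counts in control cells and 1.8 in Qk5 depletion. Against all genes tested the expectation was 1.13 called members (exact hypergeometric test, adjusted p = 0.0286), while the share called within the table, 50%, was close to the 47.6% of other genes (Fisher's exact test, adjusted p = 1). Ccnd2 (cyclin D2, 0.470-fold) was the 1 called gene of 42 cell cycle genes in the authors' deposited table. Pdia4 (0.629-fold) was the 1 called gene of 23 stress-response genes in the authors' deposited table. Ccnd2, Pdia4 and Rsad2 carried the 3′ UTR word, which long UTRs such as those of Ccnd2 (5173 nt) and Rsad2 (2660 nt) can hold by length alone. Ccng1 and Ei24 were the called members of the 19 p53 targets, both lower, and both carried the word.

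Depletion of Qk6/7 was followed mainly by falls. There were 214 genes that fell and 101 that rose in the authors' deposited table, so 32.1% of calls were upward. The sarcomere list, of which 14 genes had risen in Qk5 depletion, had no called member. Interferon-response genes fell, the inhibitors of myogenic transcription factors Id1, Id2 and Id3 fell, and 4 of 41 matrix genes rose and 1 fell.

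The genes named next are those at or above the median level. Npr3, a clearance receptor for natriuretic peptides, rose 5.43-fold in Qk6/7 depletion in the authors' deposited table (the authors' DESeq adjusted p = 1.34e-19). Postn rose 3.38-fold, Sprr1a, a cornified envelope precursor, 3.12-fold, Aldh1l2, a mitochondrial folate enzyme, 2.94-fold, and Pdlim3, a Z-disc protein, 2.40-fold in the authors' deposited table. Gdf11 (2.38-fold), Tnc (tenascin C, 2.34-fold), Pvrl1 (2.19-fold), Bahcc1 (2.17-fold) and Ccbe1 (2.14-fold) were next at such levels in the authors' deposited table. The largest fall at such levels was that of Sspn (sarcospan), a member of the dystrophin complex, at 0.254-fold (the authors' DESeq adjusted p = 1.50e-13) in the authors' deposited table. C1qtnf6 (0.281-fold), Jhdm1d (0.306-fold), the glutathione transferase Gsta1 (0.307-fold), 2310001A20Rik (0.330-fold) and Gsta2 (0.347-fold) followed in the authors' deposited table. D0H4S114 (0.361-fold), Mgst1 (0.363-fold), the quinone reductase Nqo1 (0.364-fold) and Snx10 (0.365-fold) completed the 10 in the authors' deposited table. Gsta1 and Gsta2 are near-identical paralogs whose reads may be split between them, so their separate values are uncertain. Of these 10 genes 7 had an annotated 3′ UTR, and only that of Snx10 carried GTCTTAA or GGTCTTA, a pair picked after the values were seen. Of the 187 lowered genes with an annotated 3′ UTR, 37.4% carried either word, against 15.1% of the other genes of the table (Fisher's exact test, two-sided, p = 1.16e-10), again with words found in these same lowered genes.

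All 8 called interferon-response genes fell in Qk6/7 depletion, among them Usp18 (0.112-fold), Gbp2 (0.192-fold), Ifit3 (0.206-fold) and Gbp3 (0.255-fold) in the authors' deposited table. Their levels were low: Usp18 went from a mean of 13.4 normalized counts in control cells to 1.5, and Gbp3 from 36.3 to 9.3. Of the list's members in the table only Ddx58 reached the median level, so the list could not be tested at that level. Of the 10 members in the table, 80% were called against 29.9% of other genes (Fisher's exact test, adjusted p = 0.0213), and 0.72 were expected among all genes tested (exact hypergeometric test, adjusted p = 8.85e-06). These p-values, too, take genes that fell together as independent. At adjusted p 0.01 the list's Fisher test had an adjusted p of 0.115. Id2 (0.559-fold), Id1 (0.564-fold) and Id3 (0.592-fold) fell and Myf5, a myogenic factor of proliferating myoblasts, rose 1.88-fold in the authors' deposited table, 4 of 20 myogenic regulators (exact hypergeometric test, adjusted p = 0.00465; Fisher's exact test within the table, adjusted p = 0.234). The 3 Id genes and Ctgf (1.82-fold) were likewise the 4 called members of the TGF-beta list in the authors' deposited table. Postn, Tnc, Fbn1 and Col8a1 rose and Col6a1 fell among 41 matrix genes (exact hypergeometric test, adjusted p = 0.00783; Fisher's exact test within the table, adjusted p = 0.486). The p53 targets Trp53inp1 (0.422-fold), Btg2 (0.470-fold) and Eda2r (0.553-fold) fell, and the stress genes Chac1 (2.45-fold) and Trib3 (1.84-fold) rose, in the authors' deposited table. Celf2, an RNA-binding splicing regulator, was lower (0.551-fold), Runx2 of the osteoblast list was higher (1.84-fold), and Cd68, a macrophage marker, was lower (0.341-fold) in the authors' deposited table. Celf2, Col6a1, Trp53inp1 and Eda2r carried the 3′ UTR word. The UTRs of Celf2 (7381 nt), Trp53inp1 (4420 nt) and Eda2r (3634 nt) are long, against a median of 1455 nt for lowered genes. Long UTRs can hold the word by length alone.

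None of the 17 sarcomere genes in the table was called by the authors' DESeq test in Qk6/7 depletion, with 6 at an unadjusted p under 0.05, against 30.9% of other genes (Fisher's exact test, adjusted p = 0.0213). The list's Fisher test had an adjusted p of 0.492 at adjusted p 0.01 and of 0.411 with genes at or above the median level. The low share of calls follows at least in part from the table's cut, since a gene enters it by an adjusted p under 0.1 in either comparison. All of the 17 but Tnnt1 enter it by Qk5 depletion. Among all genes tested only 0.67 called members of the list were expected, so the lack of calls shows no shortage. The lists of reported Qk RNA targets, smooth muscle and cytoskeleton, cholesterol and fatty acid synthesis, ribosomal proteins, replication-dependent histones, adipocyte markers, and oligodendrocyte and Schwann markers, 7 of the 19, had no member among the genes of the expression table. For genes outside it nothing more than an adjusted p of at least 0.1, or no test, is known here.

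**Figure D1:**
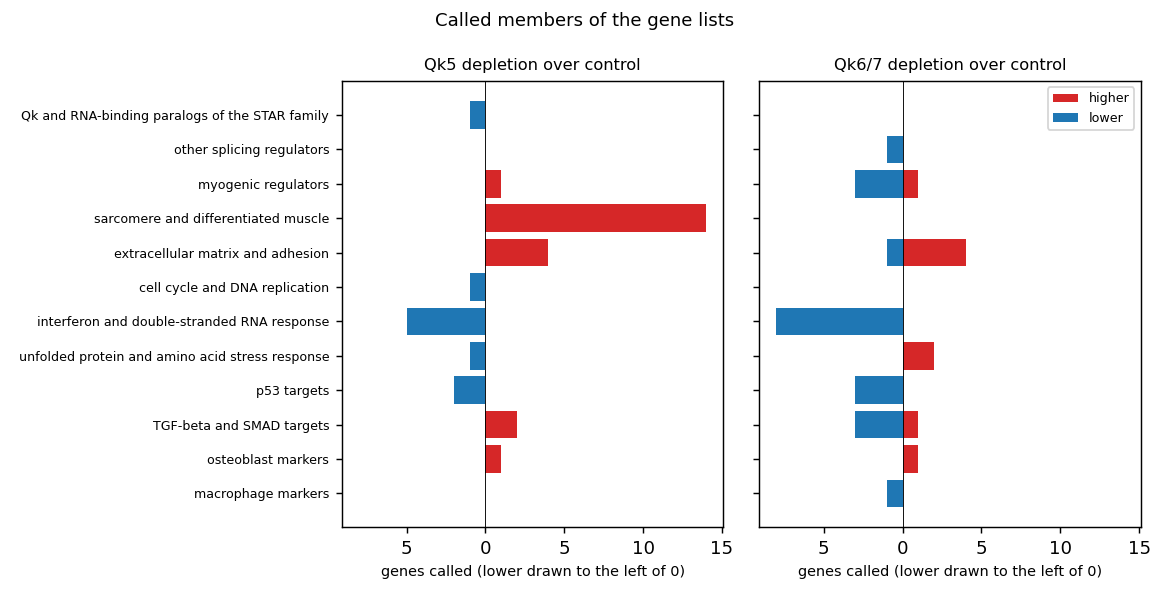
Called members (the authors' deposited adjusted p under 0.05) of the gene lists with at least 1 call, as numbers of genes on the horizontal axis, drawn to the right where higher and to the left where lower than control. The sarcomere list has 14 members higher in Qk5 depletion and 0 in Qk6/7 depletion.

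Both depletions together called 758 genes, of which 50 were called in both. Of these 33 moved in the same direction and 17 in opposite directions, and all 17 rose in Qk5 depletion and fell in Qk6/7 depletion. Among them Hpgd, which degrades prostaglandins, was 3.37-fold in Qk5 and 0.367-fold in Qk6/7 depletion, and the sodium channel gene Scn7a 4.10-fold and 0.501-fold, in the authors' deposited table. Cck (cholecystokinin) stood at 1.88-fold and 0.205-fold, Defb42 at 2.47-fold and 0.289-fold and Hmgcll1 at 2.28-fold and 0.317-fold in the authors' deposited table. No gene fell in Qk5 and rose in Qk6/7 depletion by the authors' DESeq adjusted p, where independent lists give 0.81. At an unadjusted p under 0.05, 10 genes of the table did, against 73 that rose in Qk5 and fell in Qk6/7 depletion. The larger numbers of Qk5 rises and Qk6/7 falls in the table favour the latter direction.

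By the approximate test of the difference, 619 of 1033 genes differed between the depletions, 465 higher in Qk5 and 154 higher in Qk6/7 depletion. Genes are in the table because 1 of their 2 p-values was small, and the standard error comes from that p-value. The choice favours a difference, so the count is no rate of isoform-specific response. Among genes at or above the median level the differences higher in Qk5 depletion were led by Plin4, D0H4S114, Slc40a1, Dhrs3 and C1qtnf6, with Plin4 at 2.31 on the log2 scale. Those higher in Qk6/7 depletion were led by Npr3 (-1.99 on the log2 scale), Dusp9, Psrc1, Laptm4b and Rnd1. Of the 443 genes called in Qk5 depletion alone 317 differed, and of the 265 called in Qk6/7 depletion alone 171 did. In the sarcomere list all 17 members in the table had the higher log2 fold in Qk5 depletion, with medians of 1.48 and 0.39, and 10 of them differed, a contrast that the table's cut favours since nearly all of them are in the table by their Qk5 adjusted p.

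Fisher's exact test found more shared calls than independent lists give. In the same direction 19 genes rose in both where independent lists give 2.2 (Fisher's exact test, adjusted p = 2.04e-12), among them Postn, Fbn1, Npnt, Pdlim3, Sprr1a and Ctgf. Another 14 fell in both where independent lists give 1.72 (Fisher's exact test, adjusted p = 3.72e-09), among them Ifit1, Ifit3, Rsad2, Aldh3a1, Gsta2 and Gsta3. The controls were the same libraries in both comparisons and could not be divided. In simulated groups with no effect and shared controls, genes past the p-value limits of the calls gave means of 0.42 raised and 0.41 lowered in both, at most 4 each, from fewer calls than in the data. With lists of the same sizes as the called ones the means were 24.76 raised (12 to 38 over the draws) and 21.67 lowered (8 to 36). Filling lists of those sizes from unchanged groups took genes short of the p-value limits of the calls, as if every call were noise. That simulation therefore cannot say how much of the same-direction overlap comes from the shared controls, which stays open. Rising in Qk5 and falling in Qk6/7 was shared by 17 genes where independent lists give 4.65 (Fisher's exact test, adjusted p = 6.12e-06). Both simulations gave at most 1, which the positive correlation built into them sets in advance, so they add no support here.

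**Figure D2:**
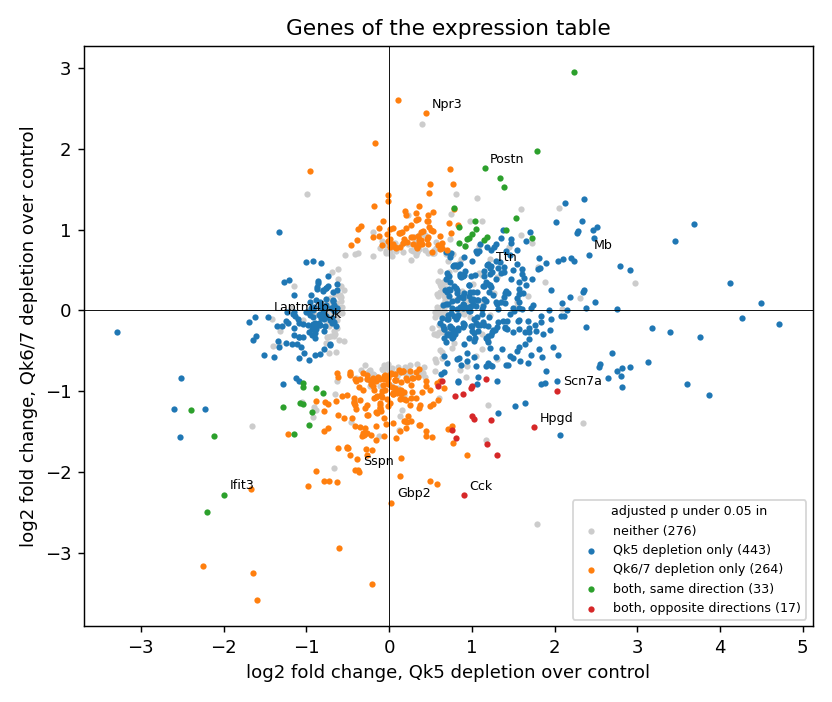
log2 fold change over control in Qk5 depletion (horizontal) and Qk6/7 depletion (vertical) for 1033 genes of the authors' deposited table with finite values, coloured by the comparison in which the adjusted p is under 0.05. The middle is empty because the table holds only genes with adjusted p under 0.1, and the 17 genes called in opposite directions lie at the lower right.

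Exon use changed in 231 bins of 192 genes by the authors' DEXSeq test over the 3 conditions. In Qk5 depletion 116 of these bins were used more and 111 less than in control cells in the authors' deposited table. The changes were larger there than in Qk6/7 depletion in 150 of the 231 bins. In Qk5 depletion 69 bins in 62 genes reached an absolute log2 change of 1, against 21 bins in 20 genes in Qk6/7 depletion.

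Bins used more after Qk5 depletion included 1 in the actin and membrane adaptor gene Sorbs2 (bin 7, chromosome 8, 46826841 to 46826933 in mm9), with a log2 change of 2.39 in the authors' deposited table (the authors' DEXSeq adjusted p = 1.60e-07). A 1717-nt bin of the dynein adaptor gene Bicd2 (bin 10, chromosome 13, 49478623 to 49480339) had 2.63 in the authors' deposited table (the authors' DEXSeq adjusted p = 3.17e-40). The last bins of Gas2l1 and Syngr1 had 2.74 and 2.30, and bins of Mtfr1, Depdc1a and Ank2 had 2.50, 2.40 and 2.38, in the authors' deposited table. A 45-nt bin of Exoc1, a subunit of the exocyst (bin 16, chromosome 5, 76986844 to 76986888), is listed at 13.79, an extreme estimate that is no bound, in the authors' deposited table. A 45-nt bin on chromosome X (34460364 to 34460408), in a gene whose symbol the table holds as a date, is likewise listed at 2.89 in Qk5 and -9.84 in Qk6/7 depletion in the authors' deposited table. Rai14, a reported Qk target that encodes an actin-associated protein, had 1 called bin (bin 8, chromosome 15, 10519014 to 10519100), at 2.14 in Qk5 and -0.38 in Qk6/7 depletion in the authors' deposited table (the authors' DEXSeq adjusted p = 1.47e-15).

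Bins used less after Qk5 depletion were led by the last bin of the casein kinase gene Csnk1d (-2.63) and a 39-nt bin of Myof, a membrane repair protein (bin 39, -2.07), in the authors' deposited table. Ppp2r5c (-1.76), Dst (-1.67), Lrrfip1, Bnip2 and 1810032O08Rik (-1.53 each), Zdhhc3 and Mark3 (-1.49 each) and Pcdh1 (-1.44) followed in the authors' deposited table. Of 53 called separate internal bins of at most 300 nt, a size usual for cassette exons, 44 changed more in Qk5 than in Qk6/7 depletion, 30 reached an absolute log2 change of 1 in Qk5 depletion and 4 did in Qk6/7 depletion. The 1 adjusted p per bin covers all conditions, so no bin is shown to change in 1 depletion and not in the other.

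In Qk6/7 depletion 94 called bins were used more and 135 less than in control cells in the authors' deposited table. Large rises included those of a pair of bins of the transcript AK017143 (1.59 and 1.48), Slc4a7 (1.34), Gas2l1 (1.23), Capzb (1.15), Celf2 (1.11), Mapk6 (0.96), Ppil5 (0.94) and Ghr (0.92) in the authors' deposited table. Capzb, an actin-capping protein and a reported Qk target, had its called bin (bin 12, chromosome 4, 138844776 to 138844888) at -0.82 in Qk5 depletion in the authors' deposited table (the authors' DEXSeq adjusted p = 0.0392). The largest falls after the bin on chromosome X were in Tacc2 (-2.09), Bsn (-1.96), the first bin of Ltbp1 (-1.78), Mapk9 (-1.50), Agpat3 (-1.49), Mettl6 (-1.47), Uspl1 (-1.46), Strbp (-1.28) and the last bin of Mapk8 (-1.19) in the authors' deposited table.

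Directly between depletions, the log2 use in Qk6/7 over Qk5 depletion was highest for Csnk1d (2.77), the bicarbonate transporter gene Slc4a7 (2.63), Bnip2 (2.21), Myof (2.02) and Capzb (1.96) in the authors' deposited table. Apart from the extreme estimates above, it was lowest for Phldb1 (-3.42), Bicd2 (-2.91) and Tacc2 (-2.70) in the authors' deposited table. The signs of the 2 changes were opposite in 118 called bins and equal in 107. Of the 69 bins past 1 in Qk5 depletion, 49 lay within 0.5 of control in Qk6/7 depletion, 8 were past 1 in both, and 4 of those 8 had opposite signs.

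The last bins of genes, those nearest the 3′ end, were called more often than others, 64 of 215 against the rest of the bins (odds ratio 8.51, Fisher's exact test, two-sided, p = 1.71e-29). They were longer, with a median of 1628 nt against 124 nt for separate internal bins. Among called last bins 50 were lower and 14 higher in Qk6/7 depletion, 78.1% against 51.5% of other called bins (Fisher's exact test, two-sided, p = 0.000288). In Qk5 depletion 25 were lower and 37 higher, 40.3% against 52.1% (p = 0.136, the same test).

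**Figure D3:**
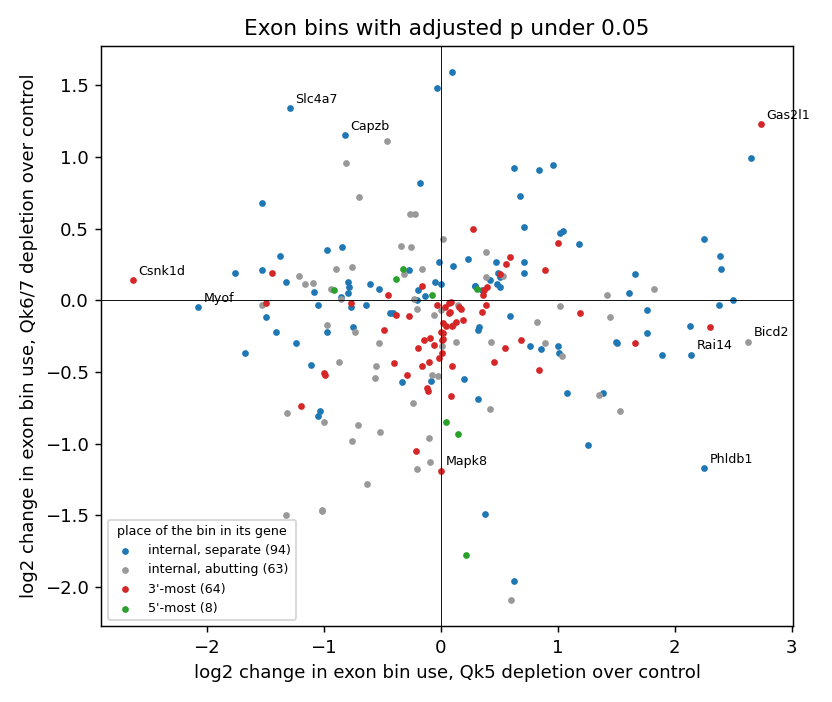
log2 change in exon bin use over control in Qk5 depletion (horizontal) and Qk6/7 depletion (vertical) for 229 of the 231 called bins of the authors' deposited table, coloured by the place of the bin in its gene. The bins of Exoc1 and of the gene on chromosome X lie beyond the axes, and the spread is wider along the Qk5 axis, with 69 bins past 1 against 21.

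Genes with a splicing call were compared with genes called in expression. Among the 31 genes present in both tables, 28 had a called bin, 28 an expression call and 25 both (Fisher's exact test, two-sided, p = 1), a test limited by the cuts on both tables. Against all genes tested, 8.77 genes with both calls would be expected by chance if the calls were independent. That figure takes every gene as equally testable for both, and 7 genes of the chromosome 2 block described below, whose copies might share reads, had both calls. An excess is thus not shown. Celf2 was among those with both.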

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

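The tests of the difference between depletions and all tests below were chosen after the results were seen, with an exception. That is the test of the 3′ UTR words in genes lowered at adjusted p between 0.05 and 0.1. Its prediction was written before that test but after the words were known to be enriched in called genes. By the approximate test of the difference, all 17 genes called in opposite directions had changes that differed between Qk5 and Qk6/7 depletion, which follows from how they were chosen. So did 488 genes called in 1 depletion alone, a choice that favours a difference, 10 members of the sarcomere list and 4 members of the interferon list.

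The first pattern is a word in the 3′ UTRs of genes lowered in each depletion, where CTCTGAA was the most enriched of 15269 words of 7 bases in genes lowered in Qk5 depletion and GGTCTTA in genes lowered in Qk6/7 depletion (permutation p = 0.001 for each, the smallest that 1000 permutations can give). UTR length would give 29.3 and 23.3 genes where 61 and 52 carried the word, and other words of the same bases reached a z of at most 4.23 against 7.43 and 4.81 against 6.76 (2.77 and 3.19 without words that share a run of 5 bases, a limit set after the values were seen), which argues against length for both words and against base composition for CTCTGAA, while base composition stays open for GGTCTTA. CTCTGAA lies in the 3′ UTR of Qk5 but also in those of Qk6 and Qk7, and GGTCTTA lies in those of Qk6 and Qk7 and not in that of Qk5, where 29.2% of all 7-base words lie in the Qk5 UTR and 9.3% in both of the others and not in that of Qk5, and of the most enriched 8-base words CCTCTGAA lies in the Qk5 UTR alone (7.88% of 8-base words do) and AGGTCTTA in none of them, while GGTCTTAA, ranked next, lies in those of Qk6 and Qk7 alone (4.32%). A candidate explanation is that some lowered genes are seed matches of the siRNAs, whose sequences were not used here. In genes lowered in Qk5 depletion at adjusted p between 0.05 and 0.1, CTCTGAA or CCTCTGA was again more frequent (54.4% against 26.4% of other genes, p = 2.31e-05, Fisher's exact test). In genes so lowered in Qk6/7 depletion, the word pair picked after the values were seen gave p = 0.0383 (Fisher's exact test). GGTCTTA alone, at 13.1% against 6.1%, gave p = 0.0552 (Fisher's exact test), which leaves the explanation open there. The other genes include those that rose, which can widen both contrasts. Among rises CTCTGAA lay in 43 genes where UTR length gives 66.8 (Qk5 depletion), and GGTCTTA in 4 where it gives 11 (Qk6/7 depletion). The loss of a Qk isoform stays open for these and the other lowered genes, and no word passed the permutation test in the rises (p = 0.173 and 0.13).

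The second pattern is the lower level of interferon-response genes in both depletions, to be weighed against high levels in the shared control libraries. Ifit1, Ifit3 and Rsad2 were called in both, and by the approximate test 0 of the 3 had folds that differed. For these, controls and depletion cannot be told apart because both comparisons use the same controls. Not every called member shows the pattern, since in Qk5 depletion Gbp2 was at 1.02-fold and Ddx58 at 1.22-fold in the authors' deposited table. A biological explanation by isoform loss was not tested further.

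The third pattern is the fall of last exon bins in Qk6/7 depletion. Split at 500 nt after a pooled test over all lengths had been seen to be uneven, the bins gave 2 answers: from 500 nt up, length can account for how often they were called (pooled odds ratio of 1.03 within 3 length classes, 95% interval 0.68 to 1.56), but under 500 nt, where 7 of 32 last bins and 76 of 3160 others were called, the ratio was 3.79 (1.44 to 9.93). Length did not give their direction, since of called bins of at least 1000 nt, 41 of 51 last bins were lower against 33 of 64 others (Fisher's exact test, p = 0.00166). That test, too, takes bins of the same gene as independent. The 151 uncalled last bins had a median log2 change of -0.06 (95% bootstrap interval -0.09 to -0.03) against -0.17 for the called ones. A loss of 3′ coverage across the Qk6/7 libraries would give such a shift, so part of the fall may be technical. These bins come only from genes kept for a bin with adjusted p under 0.1. Real shifts too small to be called would lower them too, so they cannot decide this. A shift in polyadenylation site choice by Qk6/7 was not tested.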

How the results depend on the processing

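The removal of genes that carry the 3′ UTR word and the use of the top-ranked words alone were chosen after the results were seen, and the other alternatives were fixed before the data were examined. No paired analysis was possible because the tables hold no value per replicate, and for the same reason leave-one-out fits, other splits of the samples, other count tools or normalizations, another pseudocount, single runs of replicate 1 and fits of 2 groups were not run; event types and mean levels of bins were not given either. At adjusted p 0.01, Qk5 depletion had 230 raised and 77 lowered genes and Qk6/7 depletion 50 and 121; 9 genes moved in opposite directions, 62 bins were higher in Qk6/7 depletion, and the list tests had adjusted p of 0.492 (sarcomere) and 0.115 (interferon) in Qk6/7 depletion. There the test of expression against splicing passed (Fisher's exact test, p = 0.0315), with fewer genes having both calls than expected within the table; at adjusted p 0.1 all 31 genes had both calls, which leaves no test. At adjusted p 0.1, 162 genes rose in Qk6/7 depletion, 51 were shared in the same direction and 30 in opposite directions. Among genes at or above the median level, 129 rose and 91 fell in Qk5 depletion, and 68 rose and 109 fell in Qk6/7 depletion. There 7 genes moved in opposite directions, and the sarcomere list had adjusted p of 0.0808 and 0.411 in Qk5 and Qk6/7 depletion (Fisher's exact test). The interferon list had too few members at that level to be tested. With an absolute log2 change of at least 1, 237 genes rose and 55 fell in Qk5 and 43 rose and 141 fell in Qk6/7 depletion, with 39 and 30 bins higher and lower in Qk5 and 6 and 15 in Qk6/7 depletion. Counts fall because fewer genes pass stricter settings; the cause of the lost list calls was not tested. For Qk6/7 depletion the 3′ UTR words were also tested in genes lowered at adjusted p between 0.05 and 0.1. That result was lost with GGTCTTA alone (Fisher's exact test, p = 0.0552) and with GGTCTTA or AGGTCTT (p = 0.0733, the same test). Without genes that carry the word, 53 lowered genes were left in Qk5 depletion, some with no annotated 3′ UTR to search. More genes rose than fell in Qk5 depletion, and more fell than rose in Qk6/7 depletion, in each of these settings that gave both counts.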

Other observations

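The tests and gene groups below were chosen after the results were seen. Among 47 gene cluster numbers in a row on chromosome 2, the expression table holds 14 genes (bins of 8 of them lie from 174952493 to 177691994 in mm9). These 14, among them Gm14434, Gm14308, Gm14326, Gm14391, Gm14403, Gm6710, Zfp931 and 0610010B08Rik, all rose in Qk5 depletion with log2 folds of 0.85 to 1.39 in the authors' deposited table. In Qk6/7 depletion their log2 folds ran from -0.20 to 0.47 and 0 were called by the authors' DESeq test. The other numbers are outside the table, so a rise of the whole block is not shown. Symbols such as Gm14308 stand for more than 1 gene cluster and similar copies might share reads, which was not tested, so the number of separate rises is uncertain. Bins of 7 of the 14 were also called for splicing.

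The 3 called bins of tropomyosin Tpm1 had log2 changes of 1.61, -1.21 and -1.03 in Qk5 depletion in the authors' deposited table. A pair of adjacent 76-nt bins of Tpm2 moved apart, at 0.59 and -0.64, and a 79-nt bin of Tpm3 was at -0.18 in Qk5 and 0.82 in Qk6/7 depletion in the authors' deposited table. Bin1, a membrane-bending protein of muscle, had a 93-nt bin at 2.13, and the kinase gene Map4k4 a 162-nt bin at 1.76, in Qk5 depletion in the authors' deposited table. All 5 called bins of Dclk1 were higher in Qk5 depletion, from 1.53 to 1.89, in the authors' deposited table.

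Genes of glutathione and quinone metabolism were among the falls in Qk6/7 depletion, a group picked for its falls and so not tested. Aldh3a1, Gsta1, Gsta2, Gsta3, Gsta4, Gstm1, Mgst1 and Nqo1 were called lower, with log2 folds from -0.82 for Gstm1 to -2.49 for Gsta3 in the authors' deposited table. Hmox1, an oxidative stress gene, was at 0.17 and Slc7a11, a cystine transporter, at -0.12, neither called there, in the authors' deposited table. Aldh3a1, Gsta2 and Gsta3 were called lower in both depletions, which share their controls, and the transferases are paralogs.

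A hypothesis was that genes changed in either depletion carry the Qk response words ACTAAC or ACTAAT in their 3′ UTRs. The highest z over the 4 sets of called genes was 1.66. The comparison genes had themselves changed, so the test leaves the question open.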
